A study of Homo sapiens with 15 samples.

How the data were processed

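The series holds 15 RNA sequencing libraries from KOLF2.2J, a human induced pluripotent stem cell line, and from knockout clones made in it. Cells were differentiated for 5 days towards mesoderm or endoderm, per the labels. Libraries were made from total RNA after removal of ribosomal RNA with probes (KAPA RiboErase) and sequenced on an Illumina NovaSeq X. The labels give 5 groups of 3 libraries: mesoderm with an edited ISL1 gene, wild-type mesoderm, endoderm labelled as a NKX2-1 knockout, endoderm labelled as an EOMES knockout, and wild-type endoderm. The 3 knockout libraries of a group come from separate clones, and the series design describes the wild-type libraries as biological replicates. The p-values of the fits therefore rest on a spread pooled over these clones and replicates. In mesoderm, counts differed more between ISL1 clones (chi-square per degree of freedom 8.94 to 17.3) than between wild-type replicates (3.29 to 5.43). The labels name no unedited clones, so effects of cloning cannot be told apart from those of an edit.

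The submitters' processing notes list STAR, Salmon, featureCounts and the genome build GRCh38, without versions or roles. The annotation, the strand setting and any filters are not given in the sources used here, so reads of antisense and overlapping genes cannot be assigned with certainty. The deposited gene table used for all tests holds raw counts, whole numbers of reads per gene for 38592 Ensembl genes. A second deposited table holds estimated counts per gene that are not whole numbers, and their origin in Salmon was read from the values and the list of tools rather than stated. Another deposited table holds TPM (transcript levels scaled to a fixed total per library), and each of its libraries sums to the same total. A deposited table of read classes holds counts of unmapped, multimapping, unassigned and ambiguous reads. Deposited tables per transcript and rounded copies of the estimated counts were not used. Ensembl identifiers were matched to gene symbols of GENCODE 29, which named 38568 genes and left 24 without a symbol.

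Counts were analysed in R 4.3.3 with edgeR 4.0.16. The 6 mesoderm libraries and the 9 endoderm libraries were fitted apart, because library names and sequencing lanes differ between them, and mesoderm was never tested against endoderm. Genes with too few reads were left out with filterByExpr, library sizes were scaled with TMM, and quasi-likelihood tests with robust dispersions compared group means. There was no replicate term, because the knockout libraries carry clone names and no replicate numbers. The filter left 18825 genes in mesoderm and 18724 in endoderm. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken from the quasi-likelihood F statistic. CPM values (counts scaled by library size) of the edited genes use all assigned reads, those of other genes are TMM-scaled, and both are given as mean ± SD over 3 libraries.

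Choices of samples, tests, gene lists and alternatives were fixed before the data were examined, except where the text says otherwise. The named genes were the 3 edited genes, then the 10 largest rises and the 10 largest falls among called genes. Such genes needed a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups compared. Identifiers, clone names, pseudogenes, small RNAs and long intergenic RNAs named LINC were passed over. Up to 4 members with the smallest adjusted p were also named for each list that was called or that concerned the lineage or the edited gene. Marker levels named up to 5 members per list by their level.

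The 26 gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists, with at least 5 tested members each. The lineage lists covered definitive endoderm, gut tube, lung and thyroid, primitive streak, paraxial mesoderm, lateral plate and cardiac mesoderm, second heart field, endothelium and blood, pluripotency, neuroectoderm, neural crest, amnion and trophoblast, and yolk sac endoderm. The signalling and state lists covered the Nodal pathway, WNT feedback, BMP targets, epithelial genes, mesenchymal genes, the HOX clusters, proliferation, p53 targets, stress response, and hypoxia with glycolysis. Mitochondrial mRNAs, replication-dependent histones and neighbours of the edited loci made up the remaining lists. Several lists share members, for example BMP4, ISL1, GATA6 and TFAP2A, so their results are not independent. Every list call was repeated with a correlation estimated from the data and with fry, a test of whether the members move one way on balance. Members were also counted after adjustment over the list alone.

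The alternatives were DESeq2 1.42.0, limma 3.58.1 (voom), RLE scaling, no filter, a filter of at least 1 CPM in 3 libraries, the estimated counts in rounded form, scaling without mitochondrial and structural RNAs, fits of only the groups compared, and fits leaving out each library in turn. A correction for GC content was added after the data were seen: a lowess curve (span 0.3) of each library over the GC content of the longest GENCODE transcript was taken out as an offset.

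The depth was 21.2 to 34.5 M (mega) assigned reads per library. A count of 0 in a library allowed up to 3 reads, which was 0.0870 to 0.141 CPM. Where all libraries of a group held 0 reads, folds were computed as bounds against 3 reads over the group, and where a group held 1 to 3 reads, the ratio is given with its 95% counting interval. Such intervals and floors cover counting error only.

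The tests were checked on simulated data with the depth and spread of these libraries, in which 50 genes each were changed by 1.25, 1.5, 2 and 4-fold. In the mesoderm design 13, 29, 50 and 50 of them were called, with 17 false calls among 159. In the design of the NKX2-1 comparison 27, 42, 48 and 50 were called, with 14 false calls among 181. The corresponding numbers were 25, 37, 45 and 50 for the EOMES design against wild type, with 15 false calls among 172, and 25, 36, 47 and 50 against the NKX2-1-labelled libraries, with 12 among 170. A list of 15 members raised 1.5-fold was called in each of the 4 designs, and no unchanged list was. Genes were simulated independently of each other, so this check does not cover lists with correlated members. The histone list in mesoderm, for example, had an estimated correlation of 0.870. A simulated GC trend of 0.03 log2 units per percentage point gave 5743 calls before the GC correction and 0 after it among 17348 genes.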

Results

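RNA was measured in cultures of the human induced pluripotent stem cell line KOLF2.2J after 5 days of differentiation towards endoderm or mesoderm. The cultures fell into 5 groups with n = 3 libraries each. The endoderm groups were wild type, a knockout labelled NKX2-1 (clones A03, A06 and B07) and a knockout labelled EOMES (clones A03, A04 and A10). The mesoderm groups were wild type and a knockout labelled ISL1 (clones C12, D10 and D12). Reads assigned to genes, in M (mega) reads, averaged 27.1 M ± 3.72 (SD, n = 3) in wild-type endoderm, 26.9 M ± 1.73 in the NKX2-1-labelled group and 30.6 M ± 3.46 in the EOMES-labelled group. In mesoderm they averaged 22.2 M ± 1.75 in wild type and 25.6 M ± 2.57 in the ISL1 knockout. Assigned reads per library ranged from 21.2 to 34.5 M.

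Wild-type endoderm cultures held high levels of CER1, a secreted inhibitor of Nodal, at 11982 ± 353 TPM (SD, n = 3). FGF17, a fibroblast growth factor, stood at 1508 ± 18.7 TPM and CXCR4, a chemokine receptor used as an endoderm surface marker, at 1205 ± 15.0 TPM. Of the 18 definitive endoderm genes listed, 17 exceeded 10 TPM there, while no HOX cluster gene and no paraxial mesoderm gene of the lists did. Wild-type mesoderm cultures held MIXL1, a homeobox factor of the primitive streak, at 615 ± 33.4 TPM and FGF8 at 221 ± 1.83 TPM. WNT5B stood at 190 ± 1.36 TPM in these cultures, and the caudal homeobox genes CDX2, CDX4 and CDX1 at 148 ± 7.46, 121 ± 3.50 and 111 ± 6.88 TPM. Of 20 paraxial mesoderm genes 9 exceeded 10 TPM in wild-type mesoderm, as did 14 of 27 HOX genes, led by HOXB9 at 180 ± 6.81 TPM. Mesoderm and endoderm levels were not tested against each other, because their library names and sequencing lanes differ.

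EOMES, a T-box factor of the primitive streak and early endoderm (ENSG00000163508, GRCh38 chromosome 3, 27715949 to 27722711), was nearly absent from the libraries labelled as its knockout. It had 98 to 141 reads per library there, 3.96 ± 0.725 CPM (SD, n = 3), against 17156 to 20381 reads and 686 ± 34.9 CPM in wild-type endoderm. The knockout level was 0.577% ± 0.106 of wild type (log2 fold change -7.33 ± 0.08 SE, adjusted p = 2.14e-29). In the NKX2-1-labelled libraries EOMES stood at 677 ± 16.1 CPM, 98.7% of wild type. NKX2-1, a homeobox factor of lung, thyroid and forebrain (ENSG00000136352, chromosome 14, 36516392 to 36521149), was close to the detection limit in all endoderm groups. It had 27 to 34 reads in the NKX2-1-labelled libraries, 1.17 ± 0.188 CPM, and 28 to 31 reads in wild type, 1.10 ± 0.172 CPM, with a log2 fold change of 0.12 ± 0.27 SE (adjusted p = 0.924). ISL1, a LIM homeobox factor of cardiac progenitors (ENSG00000016082, chromosome 5, 51383391 to 51394738), had 4 to 7 reads in the ISL1 knockout mesoderm and 3 to 7 in wild-type mesoderm. It was below the filter there and was not tested. ISL1 rose in the EOMES-labelled endoderm, from 2 to 11 reads in wild type to 1444 to 1809 reads, 51.8 ± 2.45 CPM (log2 fold change 8.11 ± 0.18 SE, adjusted p = 1.52e-20).

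The altered loci printed in the labels did not follow the gene names for the endoderm lines. The interval given for the NKX2-1-labelled lines, chromosome 3 from 27717205 to 27722250, lies inside EOMES and covers 91.7% of its coding bases in the annotation. The interval given for the EOMES-labelled lines, chromosome 14 from 36517273 to 36519358, lies inside NKX2-1 and covers 90.6% of its coding bases and 35.5% of its exon bases. Read counts of EOMES went with the gene name in the label. Those of NKX2-1 were few and do not show which locus was edited. They stood at 42.3% of wild type in the EOMES-labelled libraries (log2 fold change -1.11 ± 0.30 SE, adjusted p = 0.00211) and at 106.7% ± 17.1 in the NKX2-1-labelled ones. For the NKX2-1-labelled libraries the level was 83.0% on the estimated counts and 81.7% in TPM. The fall in the EOMES-labelled libraries cannot be told apart from the wider change there, where all 18 definitive endoderm genes fell. EOMES stood at 98.7% of wild type in the NKX2-1-labelled libraries and at 0.577% in the EOMES-labelled ones. These levels argue against a loss of the printed chromosome 3 interval in the NKX2-1-labelled lines. Whether the chromosome 14 interval was altered, and in which line, is not settled by these counts, because NKX2-1 had few reads. The groups were kept as named. For ISL1 the printed interval of 3 bases on chromosome 5, from 51387617 to 51387619, lies in a coding exon of that gene, and the labels name a termination codon as the edit. Gene counts alone cannot show whether the NKX2-1 or ISL1 edits were present in these libraries. The names of the mesoderm libraries contain the letters ENDO, although the description of each says mesoderm.

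**Figure D1:**
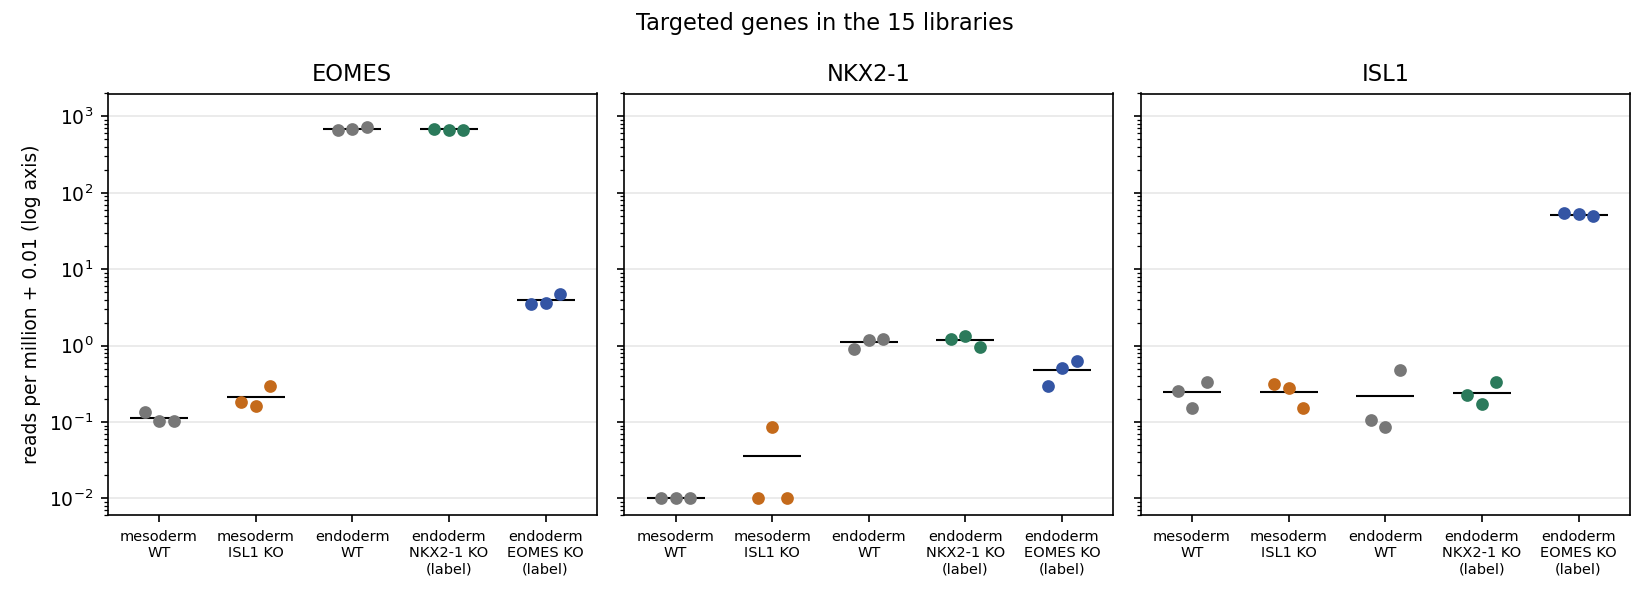
CPM of all assigned reads plus 0.01 (log axis) for EOMES, NKX2-1 and ISL1 in the 15 libraries, 1 point per library, with horizontal bars for the mean of each group of 3. EOMES points of the EOMES-labelled group lie near 3.96 CPM and those of the other endoderm groups near 677 and 686 CPM.

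The comparison of EOMES-labelled with wild-type endoderm asked how the culture changes when this factor is missing. All 18 definitive endoderm genes fell, with a median log2 fold change of -3.50, including FGF17 (-11.15 ± 0.10 SE), the receptors ERBB4 (-4.52 ± 0.06) and KIT (-3.60 ± 0.05) and the zinc finger factor GATA6 (-3.35 ± 0.06). In their place, 17 of 18 mesenchymal and matrix genes rose and 1 fell, with CDH11, a cadherin of mesenchyme, up by 11.75 ± 0.10 on the log2 scale and the collagen genes COL1A1, COL5A1 and COL1A2 up by 5.34 ± 0.07, 3.98 ± 0.06 and 3.37 ± 0.05. All 17 endothelial and blood genes rose, among them the VEGF receptor KDR (7.88 ± 0.07), the vascular proteins PLVAP (11.54 ± 0.13) and CDH5 (10.13 ± 0.14), and the ETS factor FLI1, whose ratio to wild type was 6143 (95% counting interval 1700.25 to 50730.0). These 3 lists were called by camera with adjusted p of 1.88e-35, 8.57e-41 and 1.88e-35, and with an estimated correlation the adjusted p were 0.00480, 0.000670 and 0.0133.

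Among the 10 largest rises in the EOMES-labelled cultures, COL3A1, a fibrillar collagen, had a ratio to wild type of 116997 (95% counting interval 32388 to 966085), and HAPLN1, a link protein of hyaluronan matrix, rose by 15.05 ± 0.13 SE on the log2 scale. ERG, an endothelial ETS factor, was at least 1298-fold higher, MMRN1, an endothelial and platelet protein, at least 829-fold, and VIT, a matrix protein, at least 752-fold. HAND2, a factor of heart and limb mesoderm, was at least 674-fold higher, the signalling regulator RGS1 at least 645-fold and the WNT agonist RSPO3 at least 614-fold. FRMPD4, a scaffold protein, had a ratio of 10395 (95% counting interval 1865 to 410602). Among the falls, LMX1A, a LIM homeobox factor, was at least 777-fold lower, FOXI1, a forkhead factor, at least 273-fold, ASB5 at least 232-fold and PRSS2, a trypsinogen, at least 214-fold. RGS8 fell with a ratio of wild type to knockout of 6714 (95% counting interval 1205 to 265246). ACSM4, PLSCR2, PLCXD3 and SEMA3E, a guidance cue, fell by 10.49 ± 0.26, 10.34 ± 0.10, 10.21 ± 0.12 and 9.65 ± 0.09 on the log2 scale.

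Lists of other mesodermal and extraembryonic lineages moved mostly upwards. Of 21 lateral plate and cardiac genes 17 rose and 3 fell, with BMP4 at 3.46 ± 0.05 SE, MEF2C at 8.35 ± 0.18 and PDGFRA at 2.57 ± 0.07, while GATA6 fell as above (adjusted p = 6.12e-07, and 0.0133 with an estimated correlation). Of 14 amnion and trophoblast genes 12 rose and 2 fell, among them HEY1, a Notch target (7.38 ± 0.13), TFAP2A (5.78 ± 0.21), and GATA2, with a ratio of 1289 (95% counting interval 441 to 6253). That list had an adjusted p of 2.07e-06, and of 0.0133 with an estimated correlation. Of 9 neural crest genes 7 rose and 2 fell, with ETS1 at 1.99 ± 0.04, MSX1 at 9.84 ± 0.21 and NR2F1 at a ratio of 1196 (95% counting interval 331 to 9881), for an adjusted p of 5.36e-08 and of 0.0216 with an estimated correlation. All 16 tested HOX genes rose, with HOXB8 at least 344-fold higher, HOXB6 at least 343-fold and HOXB2 up by 6.73 ± 0.22, and 9 of them had no reads in wild type. Their median was 8.76 as fitted and 7.04 with those genes at their bound (adjusted p = 6.12e-07, but 0.0697 with an estimated correlation). Of 14 second heart field genes, known to depend on ISL1 or to be bound by it, 11 rose and 3 fell, including SEMA3C at 3.77 ± 0.13 (adjusted p = 9.76e-05, but 0.0767 with an estimated correlation). Of 12 paraxial mesoderm genes 9 rose and 2 fell, including FOXC2 (8.07 ± 0.19), LFNG (3.59 ± 0.19) and WNT5B (2.66 ± 0.11), with an adjusted p of 0.00793 that became 0.110 with an estimated correlation.

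Signalling and adhesion genes moved as well. Of 12 BMP targets 10 rose and 2 fell, led by BAMBI (6.25 ± 0.07 SE), ID2 (5.11 ± 0.09) and SMAD9 (3.60 ± 0.09), with an adjusted p of 1.17e-10 and of 0.0144 with an estimated correlation. Of 16 epithelial genes 13 fell and 2 rose, with the tight junction protein CLDN7 at -5.56 ± 0.08, the splicing factor ESRP2 at -4.98 ± 0.10 and KRT19 at -1.46 ± 0.05, while KRT18 rose by 1.91 ± 0.05 (adjusted p = 1.12e-10, and 0.0385 with an estimated correlation). Of 11 Nodal pathway genes 8 fell and 2 rose, with the cofactor FOXH1 at -4.01 ± 0.14 and the Nodal inhibitor LEFTY1 at -6.29 ± 0.36 against GDF3 at 1.44 ± 0.15 (adjusted p = 0.00315, but 0.272 with an estimated correlation). Of 13 primitive streak genes 9 fell and 4 rose, with EOMES itself and FGF8 (-4.26 ± 0.13) among the falls and EVX1 at least 269-fold higher (adjusted p = 9.76e-05, but 0.218 with an estimated correlation). Of 12 WNT feedback genes 5 rose and 5 fell, with the receptor TNFRSF19 at 6.97 ± 0.07, LEF1 at 10.02 ± 0.19 and DKK1 at 5.00 ± 0.09 against AXIN2 at -1.69 ± 0.05. The median of that list was -0.12 while its mean was 1.52 and camera called it up, with an adjusted p of 0.00247 that became 0.140 with an estimated correlation.

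Of 15 pluripotency genes 9 fell and 2 rose, with SALL4 at -1.86 ± 0.05 SE, VRTN at -4.67 ± 0.09 and DNMT3B at -1.15 ± 0.04 against LIN28B at 1.19 ± 0.04 (adjusted p = 0.000213, but 0.127 with an estimated correlation). Of 9 neuroectoderm genes 6 fell and 2 rose, with OTX2 at -4.23 ± 0.07 and ZIC2 at -6.52 ± 0.08 against the intermediate filament NES at 2.51 ± 0.05 (adjusted p = 0.00136, but 0.0744 with an estimated correlation). Of 18 replication-dependent histone genes 16 rose, including H1-2 (1.88 ± 0.06), H3C2 (1.69 ± 0.05) and H4C8 (1.48 ± 0.07), with an adjusted p of 5.02e-05 that became 0.239 with an estimated correlation. Of 15 p53 targets 11 rose and 3 fell, with the cell cycle inhibitor CDKN1A at 3.81 ± 0.18 and CCNG1 at -1.51 ± 0.05 (adjusted p = 0.0285, but 0.400 with an estimated correlation and 0.0563 on the estimated counts). The other 8 lists were not called: stress response (1 rose and 12 fell of 15, adjusted p = 0.0717), proliferation (15 rose and 2 fell of 22, 0.0927), yolk sac endoderm (9 and 7 of 16, 0.102), lung and thyroid (3 and 3 of 6, 0.418), neighbours of the edited loci (5 and 6 of 14, 0.418), hypoxia with glycolysis (8 and 8 of 18, 0.692), gut tube (5 and 9 of 15, 0.722) and mitochondrial mRNAs (4 and 4 of 13, 0.946). Adjusted over the list alone, all counts were equal except for 6 falls in WNT feedback, 13 in stress response, 16 rises in proliferation and 3 in mitochondrial mRNAs. Fry called 25 of the 26 lists in this comparison, with all 18 lists called by camera among them.

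**Figure D2:**
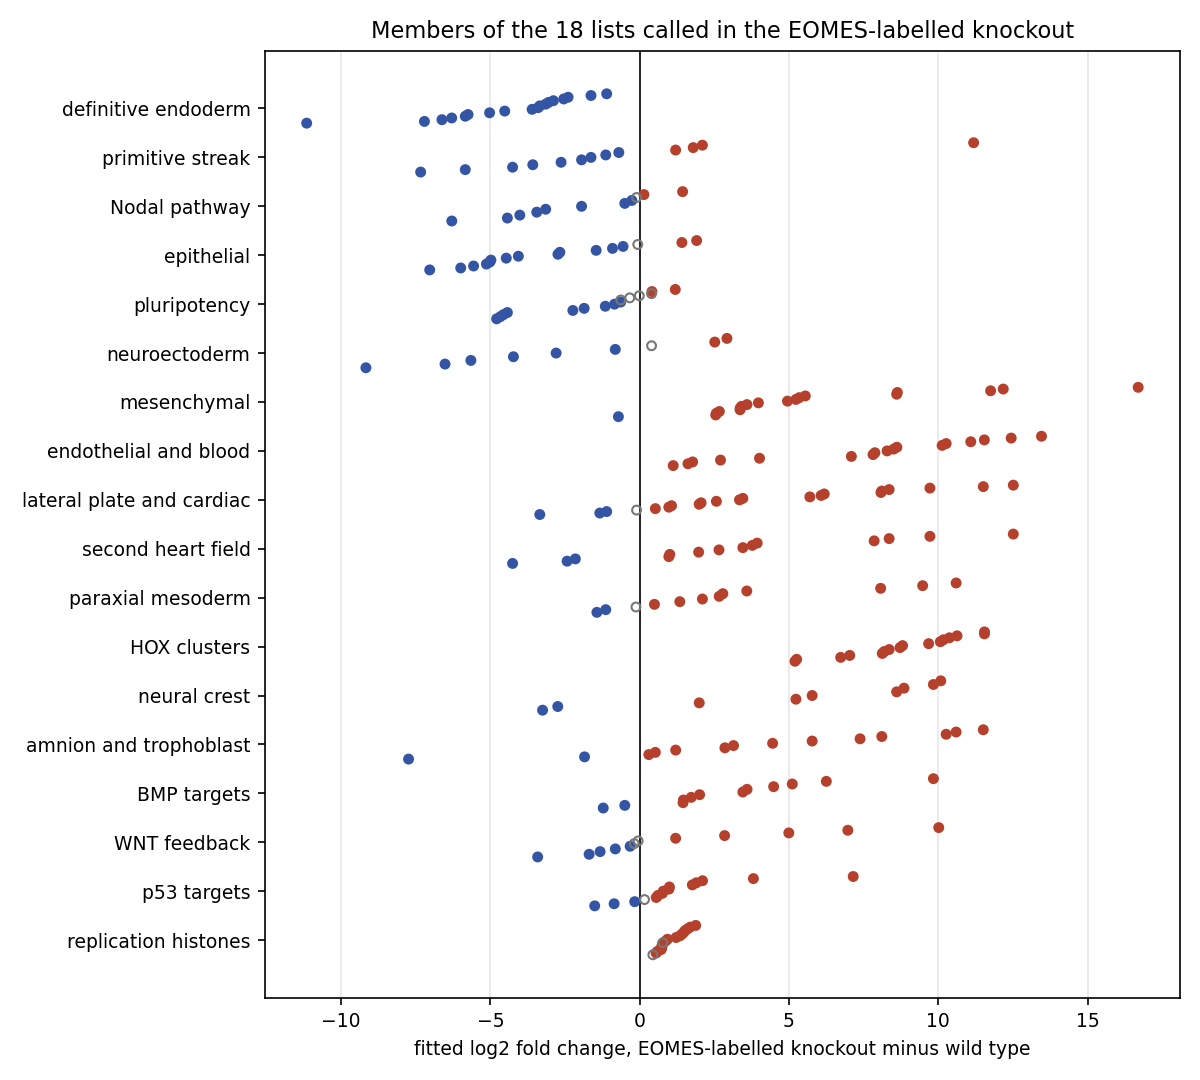
Fitted log2 fold change (horizontal axis, EOMES-labelled knockout minus wild-type endoderm, n = 3 each) of the tested members of the 18 called lists, 1 point per gene, red for called rises, blue for called falls and open circles for genes not called; points within a list are spread vertically for legibility. Genes without reads in 1 group are drawn at their fitted value, which is not a bound; all 18 definitive endoderm genes lie left of 0 and all 17 endothelial and blood genes right of it.

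In total 6713 genes rose and 7199 fell of the 18724 tested (edgeR), 2899 and 3217 of them by at least 2-fold, and NKX2-1 was among the falls (-1.11 ± 0.30 SE, adjusted p = 0.00211). The libraries of the groups did not overlap for 14304 genes, 76.4%, where chance gives 10%. The first principal component held 93.0% of the variance and placed the EOMES-labelled libraries at 157 to 166 and the others at -82.2 to -79.4. Mapped reads that matched no counted feature made up 11.5% ± 0.467 (SD, n = 3) of the EOMES-labelled libraries and 14.7% ± 1.42 of wild-type endoderm, without overlap between the groups. Whether such reads lay inside or outside genes cannot be told, because the counting settings are not given.

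The EOMES-labelled libraries were also set against the NKX2-1-labelled ones, edited clones of the same line, to compare the lines with these labels at the same stage. The same genes headed the change in this comparison: COL3A1, HAPLN1, FRMPD4, MMRN1, VIT, HAND2 and FLI1 were again among the 10 largest rises, and the 10 largest falls were again LMX1A, RGS8, FGF17, FOXI1, ASB5, PRSS2, ACSM4, PLSCR2, PLCXD3 and SEMA3E. New among the rises were the endothelial adhesion receptor SELE, at least 1330.5-fold higher in the EOMES-labelled libraries, SRPX2, at least 1014-fold higher, and HAND1, a factor of cardiac and extraembryonic mesoderm, with a ratio of 9840.1 (95% counting interval 2724 to 81258). EOMES itself stood at -7.34 ± 0.08 SE (adjusted p = 2.11e-29) and ISL1 at 7.84 ± 0.17 (adjusted p = 1.80e-20), while NKX2-1 was lower by the counts (-1.23 ± 0.30, adjusted p = 0.000734) but not called on the estimated counts (-0.58, adjusted p = 0.0919). All 18 definitive endoderm genes fell, 17 of 18 mesenchymal genes and all 17 endothelial and blood genes rose, and the adjusted p of these lists were 3.68e-36, 1.02e-40 and 1.53e-35. With an estimated correlation they were 0.00577, 0.000681 and 0.00712.

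The median and mean of WNT feedback again differed in sign (-0.13 and 1.40), with a call up. In this contrast 18 lists were called, 12 up and 6 down, and 10 remained with an estimated correlation, which included HOX (all 16 rose, adjusted p = 0.0309) and second heart field (11 rose and 3 fell of 14, adjusted p = 0.0168). The 8 lists that did not remain had adjusted p with an estimated correlation of 0.0556 for paraxial mesoderm, 0.0571 for neuroectoderm, 0.0801 for WNT feedback, 0.102 for pluripotency, 0.199 for primitive streak, 0.206 for histones, 0.280 for the Nodal pathway and 0.347 for p53 targets. In total 6787 genes rose and 7052 fell, and the libraries did not overlap for 14463 genes, 77.2%, where chance gives 10%. Both comparisons use the EOMES-labelled libraries, so they are not independent of each other.

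The comparison of NKX2-1-labelled with wild-type endoderm asked what differs in lines carrying that label. A loss of NKX2-1 was not seen in its counts, which stood at 106.7% of wild type (83.0% on the estimated counts), and the interval printed for these lines lies in EOMES. EGR1, an immediate-early zinc finger factor, was higher at 15.5 ± 2.39 CPM (SD, n = 3) against 9.11 ± 0.509 CPM, a log2 fold change of 0.77 ± 0.10 SE (adjusted p = 0.00112). MYC, a growth-promoting transcription factor, was higher at 19.9 ± 1.75 against 14.1 ± 0.705 CPM (0.50 ± 0.07 SE, adjusted p = 0.00304). SRSF5, a splicing factor, was higher at 118 ± 3.95 against 91.1 ± 1.33 CPM (0.37 ± 0.04 SE, adjusted p = 0.000148). These were the only genes that edgeR called of 18724 tested, each higher in all 3 clones than in any wild-type library, and none was lower in this fit.

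None of the 6 tested lung and thyroid genes that depend on NKX2-1 passed the test, the nearest being the lipid transporter ABCA3 at 0.27 ± 0.13 SE (adjusted p = 0.507). These genes were low in wild-type endoderm, where ABCA3 was the highest of the 16 listed at 2.07 ± 0.116 TPM, followed by NAPSA at 0.291 TPM. A fall could therefore hardly be seen, and the absence of calls does not show that NKX2-1 targets were unaffected. That list was not called (adjusted p = 0.658), and its median of 0.14 and its mean of -0.01 differed in sign. Of 15 gut tube genes none passed over all genes and 1, the liver and lymphatic factor PROX1 (-0.29 ± 0.08, adjusted p = 0.268), fell adjusted over the list alone (list adjusted p = 0.421). None of the 18 definitive endoderm genes passed, with PRDM1 at 0.13 ± 0.04 and KIT at 0.11 ± 0.05 (list adjusted p = 0.261). Camera called 5 lists at the preset correlation although no member of them passed over all genes. All 5 calls were lost with an estimated correlation (adjusted p = 0.595 for each), and fry called 0 of the 26 lists. The 18 replication-dependent histones were called down (adjusted p = 6.72e-07, but 0.595 with an estimated correlation), with H2AC20 at -0.16 ± 0.05 and H2BC9 at -0.20 ± 0.06 and 4 falls adjusted over the list alone. The 12 BMP targets were called up (adjusted p = 0.000544, but 0.595 with an estimated correlation), with ID2 at 0.50 ± 0.12, ID3 at 0.50 ± 0.11 and ID1 at 0.36 ± 0.10, and 3 rises adjusted over the list alone. Epithelial genes (KRT19 at 0.13 ± 0.05) and proliferation genes (PLK1 at 0.13 ± 0.05) were called up with the same adjusted p of 0.000544, and hypoxia with glycolysis (NDRG1 at 0.24 ± 0.09) with 0.0207, each with 0 members adjusted over the list alone. Among lists not called, the median and the mean also differed in sign for primitive streak, endothelium and blood, pluripotency, neuroectoderm and mesenchymal genes.

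An unadjusted p under 0.05 was reached by 1827 genes, where 936 were expected by chance, and the libraries did not overlap for 2981 genes, 15.9%, where chance gives 10%. Mapped reads that matched no counted feature made up 12.9% ± 0.504 (SD, n = 3) of the NKX2-1-labelled libraries, 12.4% to 13.4%, and 13.9% to 16.4% of the wild-type libraries. The count of called genes was 9 with DESeq2, 82 without a filter (51 higher, 31 lower) and 23 in a fit of these groups alone (12 higher, 11 lower). Without clone A03 it was 6 and without clone B07 it was 23 (7 higher, 16 lower). Calls with DESeq2, limma-voom, RLE scaling and the estimated counts, and without clone A03 or A06, also included lower genes. Without wild-type replicate 1 the count was 1, since EGR1 (adjusted p = 0.0669) and MYC (0.0986) were no longer called. Their log2 fold changes there, 0.75 and 0.45, were close to the 0.77 and 0.50 with all libraries. MYC was also not called by limma-voom (adjusted p = 0.0993), at a log2 fold change of 0.50.

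The comparison of ISL1 knockout with wild-type mesoderm asked how early mesoderm differs in lines with this edit, and it showed small differences. ISL1 itself was too low to be tested, with 3 to 7 reads per library in wild type. With so little ISL1 RNA after 5 days, the comparison could hardly show an effect of its loss at that stage. HOXB1, an anterior HOX gene expressed in the hindbrain, was higher in the knockout by 0.71 ± 0.09 SE on the log2 scale, at 29.8 ± 1.77 CPM (SD, n = 3) against 18.2 ± 2.01 CPM. SEMA3C, a guidance cue needed in the cardiac outflow tract, was higher by 0.63 ± 0.12 and ID3, a BMP-induced inhibitor of helix-loop-helix factors, by 0.42 ± 0.06. ABCB1, a drug efflux pump, fell by 1.03 ± 0.16, from 6.96 ± 1.09 to 3.41 ± 0.484 CPM. The adjusted p of these 4 genes lay between 0.0243 and 0.0459.

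The other named rises were PCDHA11, a clustered protocadherin (0.87 ± 0.13 SE), the matrix proteoglycan SPOCK1 (0.76 ± 0.13), the glycosyltransferase GALNT17 (0.90 ± 0.15), the WNT inhibitor DKK4 (0.73 ± 0.14), the kinesin KIF1A (0.60 ± 0.11), the streak homeobox gene EVX1 (0.55 ± 0.10) and the autophagy kinase ULK1 (0.50 ± 0.09). ZBTB47-AS1, an antisense RNA whose reads depend on the unstated strand setting, was lower (-0.70 ± 0.10). The other named falls were the ubiquitin ligase MARCHF1 (-0.72 ± 0.11), PLPPR5 (-0.59 ± 0.12), MBLAC2 (-0.56 ± 0.10), the kinase substrate PLEK (-0.49 ± 0.08), the secretory pathway protein TMED7 (-0.48 ± 0.08), the small GTPase RAP2C (-0.45 ± 0.09) and the ubiquitin-conjugating enzyme UBE2D1 (-0.45 ± 0.08). After each library's trend over GC content was taken out, a step added after the data were seen, GALNT17, DKK4, KIF1A, EVX1, ULK1, MARCHF1, PLPPR5, MBLAC2, TMED7, RAP2C and UBE2D1 were no longer called, while HOXB1, SEMA3C, ID3, ABCB1, PCDHA11, SPOCK1, ZBTB47-AS1 and PLEK still were.

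**Figure D3:**
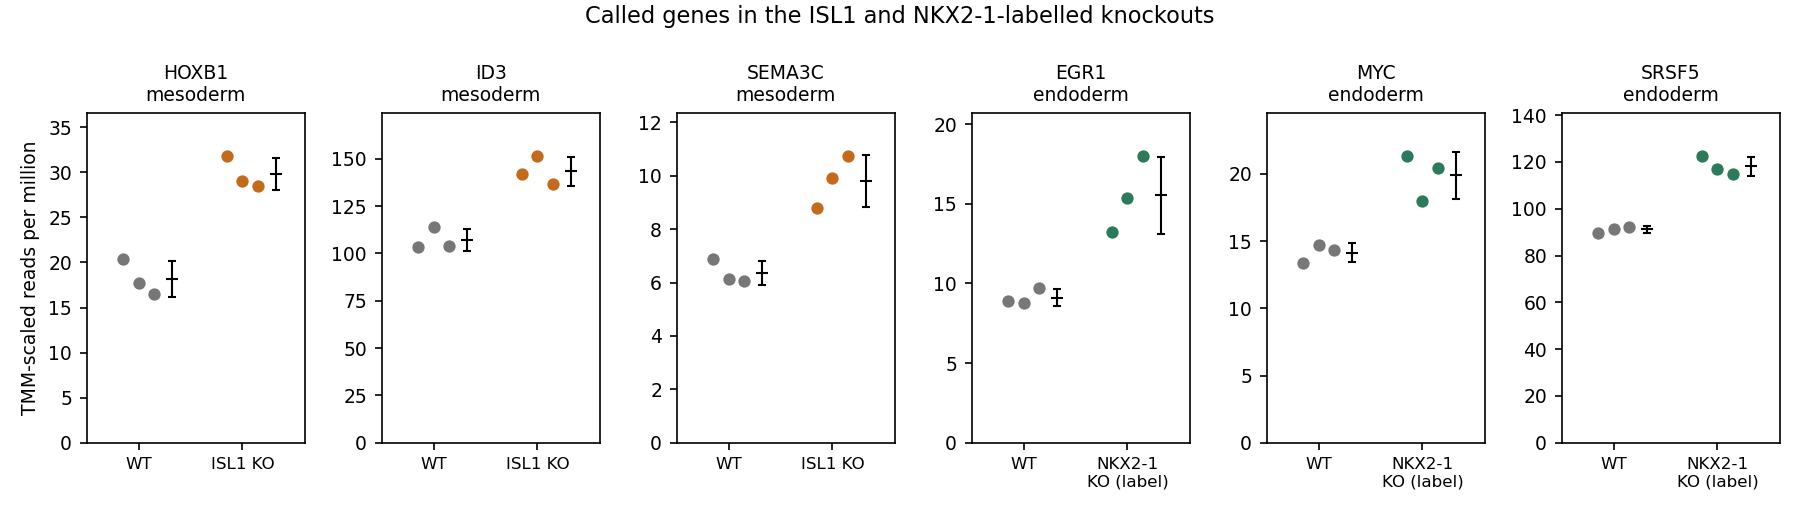
TMM-scaled CPM (vertical axis from 0) of 3 genes called in the ISL1 knockout mesoderm and of the 3 genes called in the NKX2-1-labelled endoderm, 1 point per library, with the mean and SD (n = 3) beside the points. HOXB1 averages 29.8 CPM in knockout and 18.2 CPM in wild type, and EGR1 averages 15.5 against 9.11 CPM.

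Of the 9 tested second heart field genes, SEMA3C rose and 8 did not pass, among them BMP4 at 0.50 ± 0.12 SE (adjusted p = 0.0761) and BMP7 at -0.32 ± 0.07 (adjusted p = 0.0634). Adjusted over the list alone, 2 rose and 2 fell, and the list was not called (adjusted p = 0.766). None of 13 lateral plate and cardiac genes passed, 3 rose adjusted over the list alone, and the list had an adjusted p of 0.133, with ACTC1 at 0.49 ± 0.14 and GATA4 at 0.30 ± 0.09. The list of 26 tested HOX genes, with HOXB1 among them, held no fall over all genes. Adjusted over the list alone, 5 fell, including HOXC8 (-0.57 ± 0.14) and HOXC6 (-0.41 ± 0.11), and the list was not called (adjusted p = 0.629). Among the other lists not called, the median and the mean differed in sign for neural crest (-0.16 and 0.05), endothelium and blood (-0.01 and 0.15), pluripotency (-0.01 and 0.03) and neighbours of the edited loci.

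Camera called 8 lists at the preset correlation, all up, though few members passed over all genes. All 8 calls were lost with an estimated correlation, where the adjusted p were 0.644 for proliferation and for hypoxia with glycolysis and 0.597 for the other 6, and fry called 0 of the 26. The lists were replication-dependent histones (0 of 18 rose, adjusted p = 2.42e-07), mitochondrial mRNAs (0 of 13, 3.22e-07), BMP targets (ID3 alone of 12, 4.68e-05), proliferation (0 of 22, 0.00268), epithelial genes (0 of 15, 0.00396), primitive streak (EVX1 alone of 12, 0.0129), paraxial mesoderm (0 of 13, 0.0129) and hypoxia with glycolysis (0 of 18, 0.0193). Removal of the GC trend also ended the calls of primitive streak (adjusted p = 0.644, median log2 fold change from 0.16 to 0.02) and paraxial mesoderm (0.903, from 0.14 to 0.01). Adjusted over the list alone, 6 histones rose, including H2BC4 (0.19 ± 0.06 SE) and H3C8 (0.37 ± 0.10), as did 4 BMP targets, including MSX1 (0.30 ± 0.07) and ID1 (0.38 ± 0.08), and 5 epithelial genes, including KRT8 (0.23 ± 0.06). So did 3 primitive streak genes, including SP5 (0.20 ± 0.06), 2 paraxial genes, FOXC1 (0.38 ± 0.08) and DLL1 (0.26 ± 0.06), and 1 proliferation gene, PLK1 (0.25 ± 0.06). No member of the mitochondrial or hypoxia lists did so, where MT-CO3 stood at 0.35 ± 0.10 and NDRG1 at 0.41 ± 0.13. The share of assigned reads from mitochondrial genes was 1.32% ± 0.210 (SD, n = 3) in the knockout and 1.04% ± 0.0958 in wild type. Mapped reads that matched no counted feature made up 22.4% ± 0.624 of the knockout libraries and 24.6% ± 0.270 of wild type.

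In total edgeR called 96 of 18825 genes, 26 higher and 70 lower, with a median absolute log2 fold change of 0.37. An unadjusted p under 0.05 was reached by 3779 genes, where 941 were expected by chance, and the libraries did not overlap for 4954 genes, 26.3%, where chance gives 10%. The count was 387 with DESeq2 (2839 unadjusted), 0 with limma-voom (3737 unadjusted), 1579 without a filter, 35 with the filter of 1 CPM, 23 on the estimated counts and 13 after removal of the GC trend. The balance of directions differed between settings. There were 865 higher and 714 lower genes without a filter, 803 and 707 without clone D12, and 7 and 6 after removal of the GC trend. Leaving out a library gave 1 without wild-type replicate 1, 30 without replicate 3, 0 without replicate 4 (2407 unadjusted) and 0 without clone C12 (3560 unadjusted), but 591 without clone D10 and 1510.0 without clone D12.

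**Figure D4:**
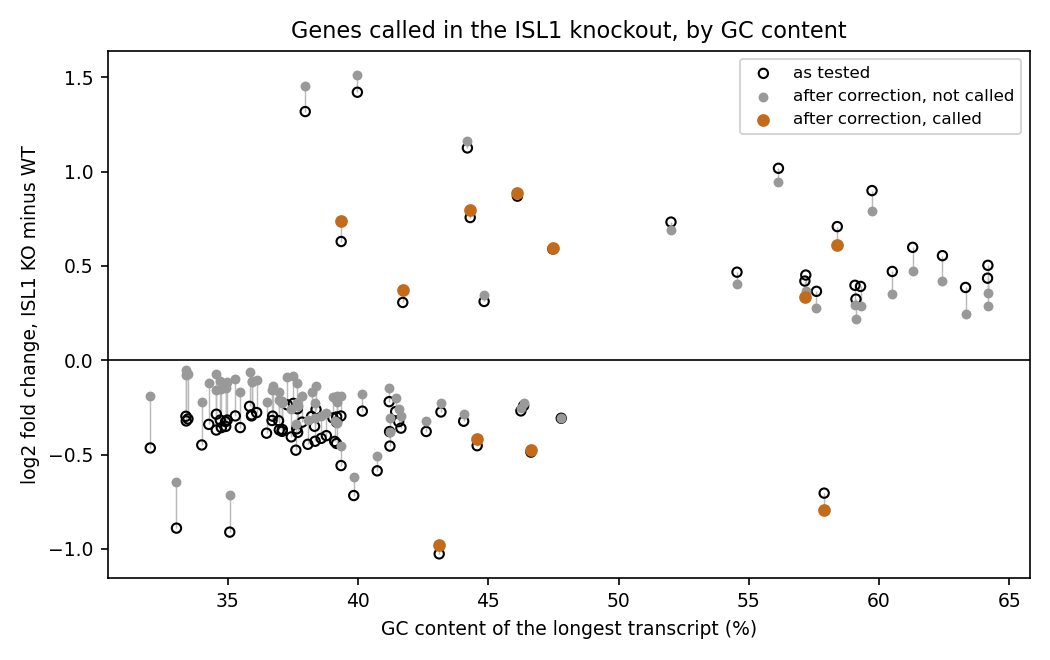
Log2 fold change (ISL1 knockout minus wild-type mesoderm, n = 3 each) of the called genes against the GC content of their longest transcript in percent, 1 gene per pair of points, open circles as tested and filled circles after each library's GC trend was taken out, orange where still called. Called genes that were higher have a median GC content of 57.2% and those that were lower 37.8%, against 48.0% for all genes tested.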

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

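The tests of leftover wild-type cells and of mesoderm RNA in the EOMES-labelled cultures were written after the values they use had been seen, and the GC content correction was added after the results had been seen.

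Reads that overlapped more than 1 gene, which enter no gene count, made up a larger share in every knockout library than in every wild-type library of the same lineage. They were 4.08% ± 0.0564 (SD, n = 3) of reads in the ISL1 knockout against 3.94% ± 0.0909 in wild-type mesoderm. In endoderm they were 4.44% ± 0.0310 in the NKX2-1-labelled and 4.63% ± 0.0215 in the EOMES-labelled libraries against 4.27% ± 0.105 in wild type. They stand here because they are a difference in a class of reads that no comparison uses, and no explanation for them was tested.

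The EOMES-labelled cultures lost endoderm genes such as FGF17 and gained genes of matrix and vessels such as HAPLN1. Wild-type endoderm cells left in these cultures are argued against as the source of the endoderm RNA that remained: of the 100 most abundant genes among those that fell at least 2-fold, 26 lay below the median share of 20.7% of their wild-type level divided by 3, and 6 lay under 1%, down to 0.0428% (FGF17). RNA or cells from the mesoderm cultures are argued against as the source of the rises, since 78.6% of the genes that rose at least 2-fold and had a TPM above 0, 2247 of 2857, had a higher TPM than in wild-type mesoderm. The 129 genes with at least 10 TPM in wild-type mesoderm and under 1 TPM in wild-type endoderm ranged from 0.172% (FGF19) to 26120.5% (HAPLN1) of their mesoderm level. A change of cell identity in cells without EOMES stays open and was not tested, and other sources of cells were not tested either.

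The genes called in the ISL1 knockout were few and small in effect, with HOXB1, SEMA3C and ABCB1 among them, and their number of 96 became 1, 30 and 0 without wild-type replicates 1, 3 and 4, and 0, 591 and 1510.0 without clones C12, D10 and D12. Their log2 fold changes did not rest on clone D10 alone. The median ratio of those without it to those with it was 0.883 (quartiles 0.831 to 0.937), with 95 of 96 still called. The genes were picked by a test that favours agreement between clones, so this ratio cannot exclude an influence of that clone. Gene length is argued against by a ratio of 0.998 (0.962 to 1.03) after its trend was taken out, which left 72 calls, 65 of them among the 96. GC content cannot be told apart from the edit: the ratio was 0.707 (0.513 to 0.863), the median absolute log2 fold change went from 0.37 to 0.26 while the median SE went from 0.0663 to 0.0605, so that calls ended because folds shrank, and 11 of the 96 genes were called after it. Genes under 40% GC minus those over 55% gave 0.16, 0.04 and 0.17 in the wild-type libraries and -0.06, -0.20 and -0.12 in the knockout clones, a split that follows the groups. An effect of the ISL1 edit stays open beside it, but ISL1 had only 3 to 7 reads per library in wild-type mesoderm. The comparison could therefore hardly show an effect of ISL1 loss at this stage.

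EGR1, MYC and SRSF5 were higher in the NKX2-1-labelled libraries, and EGR1 and MYC belong to the immediate-early genes. Handling at harvest is argued against as the whole cause, because the other 24 immediate-early genes had a median log2 fold change of 0.0619 (quartiles 0.00 and 0.18), with 18 higher, 6 lower and 0 past the threshold by edgeR. Their list test gave p = 0.000463 at the preset correlation, 0.108 with an estimated correlation and 0.0931 by fry, so a smaller shift of the whole class stays possible. EGR1, MYC and SRSF5 did not rest on wild-type replicate 4 alone, which stood apart in its read classes. Without it the median ratio of their log2 fold changes was 1.02 (1.02 to 1.06), with 3 of 3 genes still called. They were picked with that library included, by a test that favours agreement within groups, so its influence is not excluded. Without wild-type replicate 1 EGR1 (adjusted p = 0.0669) and MYC (0.0986) were no longer called, though their log2 fold changes were 0.75 and 0.45 against 0.77 and 0.50, while 6 genes were called without clone A03 and 23 without B07, and the NKX2-1 edit as a cause was not tested further.

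With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes, 1 split, the real one, gave as many calls in each comparison: 96 against a highest other of 0 for ISL1, 3 against 1 for NKX2-1, 13912 against 0 for EOMES and wild type, and 13839 against 0 for EOMES and NKX2-1. For lists, 3 splits gave as many calls in the ISL1 comparison (8, highest other 9), 4 in the NKX2-1 comparison (5, highest other 7), and 1 in each EOMES comparison (18, highest others 14 and 16).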

How the results depend on the processing

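The GC content correction was chosen after the results had been seen, and the other alternatives here were planned.

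In both EOMES comparisons the counts of genes stayed within 1.5 times the reported ones under all alternatives: 12402 to 15525 against wild type and 12348 to 15417 against the NKX2-1-labelled libraries. The balance of directions depended on the scaling. Against wild type 6713 rose and 7199 fell as reported, but 6959 and 6922 with RLE scaling and 6644 and 6590 with DESeq2. Against the NKX2-1-labelled libraries 6787 and 7052 became 6937 and 6880 with RLE scaling. Fry, which asks whether the members move one way on balance, called 25 of the 26 lists in each, with all 18 reported lists among them. Camera with an estimated correlation called 8 and 10 lists instead of 18 in each. The size of the correlation does not account for all of this loss. For amnion and trophoblast against wild type the estimate, 0.0101, was close to the preset 0.01. Even so, the unadjusted camera p went from 7.15e-07 to 0.00257.

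The ISL1 comparison depended on the processing. Its 96 genes became 387 with DESeq2, 0 with limma-voom (3737 at an unadjusted p under 0.05), 1579 with no filter, 35 with CPM of at least 1 in 3 libraries, 23 on the Salmon counts and 13 with the GC content trend taken out, and the cause was not tested except for the last. It became 65 with RLE scaling and was 96 without mitochondrial and structural RNAs. Leaving out a library gave 0 to 1510.0 genes: 1 without wild-type replicate 1, 30 without replicate 3, 0 without replicate 4, 0 without clone C12, 591 without D10 and 1510.0 without D12. Its 8 lists became 0 with an estimated correlation and 0 with fry. With the GC content trend taken out 8 lists were called, 6 of them shared: primitive streak (adjusted p from 0.0129 to 0.644) and paraxial mesoderm (0.0129 to 0.903) were lost, and HOX and stress response were called down (both 0.0265, and 0.816 with an estimated correlation).

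In the NKX2-1 comparison the 3 genes became 9 with DESeq2, 82 with no filter and 23 with only the 2 groups, and the cause was not tested. Leaving out a library gave 1 (without wild-type replicate 1) to 23 (without clone B07), and 6 without clone A03. Its 5 lists became 0 with an estimated correlation and 0 with fry. NKX2-1 in these libraries, 106.7% of wild type in the counts, was 83.0% on the Salmon counts and 81.7% in TPM. Genes not called there reversed: EOMES (0.00) was -0.0065 with CPM of at least 1 in 3, -0.0086 on the Salmon counts and -0.0046 with the GC content trend taken out, and -0.0194 to 0.0202 without a library. NKX2-1 (0.12) was -0.25 on the Salmon counts and -0.0045 to 0.24 without a library, and ISL1 (0.27) was -0.11 to 1.39.

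The named genes made 265 pairs of a gene and a comparison, in which a gene can recur. Called pairs kept direction and call in 2755 values and lost the call in 132, of 24 pairs. Pairs not called gained a call in 82 values, of 34 pairs. Called lists kept it in 484 values and lost it in 55, and 10 gene values had no adjusted p.

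No paired analysis was possible because the knockout libraries carry clone names and no replicate numbers of their own that pair them with wild-type libraries. Depth limits genes such as NKX2-1 and ISL1, which had at most 34 and 11 reads per library outside the EOMES-labelled group.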

Other observations

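The genes in the following paragraph were chosen after their values were seen. They were the 10 most abundant genes outside all lists in each direction among called genes that rose or fell at least 4-fold. The tests of genes beside the edited loci were also chosen then.

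In the EOMES-labelled cultures the link protein HAPLN1 stood at 3403 ± 169 TPM (SD, n = 3) against 0.0725 in wild type, tropomyosin TPM1 at 3159 ± 132 against 397, RGS5, a marker of pericytes, at 1603 ± 40.1 against 12.3, and smooth muscle actin ACTA2 at 819.6 ± 63.2 against 0.799. The integrin chains ITGB1 and ITGAV stood at 1271 and 926 against 197 and 59.4 TPM, the calcium-binding protein S100A11 at 2418 against 382, the matrix protease MMP2 at 906 against 8.45, the actin-binding protein CALD1 at 762 against 96.1, and the imprinted RNA H19 at 1115 ± 74.7 against 0.549. Among the falls, the WNT receptor FZD5 went to 21.1 from 1926 TPM, the retinoic acid hydroxylase CYP26A1 to 17.9 from 1783, IFITM1 to 82.2 from 1445 and the apolipoprotein APOC1 to 87.8 from 1057. NUDT4, PTGR1, MGST2, PODXL, MRPL22 and SERPINB9 went to 97.3, 96.4, 34.9, 149, 69.6 and 31.7 from 1004, 912, 874, 833, 731 and 629 TPM. All 20 genes were called in this comparison because a call was part of the rule that picked them.

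In the ISL1 knockout the collagen gene COL1A2 was higher by 0.31 ± 0.05 SE (adjusted p = 0.0312), the Nodal cofactor FOXH1 by 0.39 ± 0.08 (0.0496), and SKIL, an inhibitor of SMAD signalling, was lower at -0.30 ± 0.06 (0.0492). These genes were also named after their values were seen. After the GC content trend was taken out COL1A2 was still called at 0.37 ± 0.05, while FOXH1 at 0.25 ± 0.07 (adjusted p = 0.249) and SKIL at -0.05 ± 0.06 (0.726) were not, because their folds shrank. In the same fit SFN, an epithelial 14-3-3 protein, and the growth factor FGF19 were called lower at -0.40 ± 0.06 and -0.43 ± 0.07.

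Genes next to the edited loci were counted as well. ISL1-DT, a transcript divergent from ISL1, had 12 to 25 reads in the ISL1 knockout against 5 to 8 in wild-type mesoderm, and 270 to 296 in the EOMES-labelled libraries against 0 to 2 in wild-type endoderm (exact permutation p = 0.1 in both, the smallest that 3 against 3 can give). SFTA3, which overlaps the NKX2-1 locus, had 8 to 11 reads in the NKX2-1-labelled libraries against 1 to 4 in wild type (exact permutation p = 0.1) and 2 to 16 in the EOMES-labelled ones (p = 0.3 by the same exact test). NKX2-1-AS1 had 1 to 6 against 0 to 1 reads in the NKX2-1-labelled comparison (exact permutation p = 0.2). PAX9 had 6 to 21 in the EOMES-labelled against 15 to 46 in wild-type libraries (exact permutation p = 0.1). The strand setting of the counts is not given, so reads of these overlapping genes cannot be assigned with certainty.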
